A study of Mus musculus with 14 samples.

How the data were processed

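RNA from fluorescence-sorted cells of the mouse cerebral cortex was measured on Affymetrix exon arrays, 4 from SOD1 G93A mice and 3 from control mice, all at postnatal day 120. Per the labels' protocols, the whole cortex was dissociated, single cells were gated on green fluorescence, RNA with an integrity score above 5 was kept, and the RNA was amplified linearly and labelled with biotin by a NuGEN kit. The values deposited by the authors are on a log2 scale, and RMA and Partek are named in the submitters' processing notes. RMA corrects background, normalises by quantiles and summarises probes. Settings, versions and the genome build are not given in the sources used here. Each of the 7 arrays has a column in a transcript-level table and a column in an exon-level table, so the tables are separate summaries of the same measurement and were never counted as separate replicates. The design note counts 4 mutant mice and 3 controls, but the labels do not tie each array to a single animal, so p values measure the spread between these arrays.

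The medians of the transcript-level columns were 5.38, 5.39, 5.34 and 5.32 for SOD1 G93A 1 to 4 and 5.37, 5.27 and 5.37 for Control 1 to 3. In the exon-level table they were 3.69, 3.74, 3.87 and 4.67 for SOD1 G93A and 3.86, 4.29 and 4.36 for control, so this table is not aligned between arrays. The scale follows from the notes and the range of the values, while any centring and the choice of the exon-level rows stay unknown. After rounding, 99.0% of the exon-level values also occur somewhere in the transcript-level table. Matches can arise by coincidence in a table of this size, which was not tested, so this share alone does not show common entries. Some values recur on unrelated rows of an array, such as 4.17503 for Lcn2 and S100a8 on Control 1. On SOD1 G93A 1, 4.34577 stands for Lpl and for exon-level row 4629661. The cause of such repeats was not tested. The tables share 0 row identifiers. At the transcript level, 17.5% of rows hold exactly equal values on 2 or more arrays, and 165 rows hold the same value on all 7. Pearson correlations between arrays, computed across rows, ran from 0.882 to 0.956, with a median of 0.899 within groups and 0.901 between groups. No array's values were identical to another's, and all were kept as separate replicates. No scan date or batch is given in the sources used here. Arrays have no read depth, and their number limits the precision.

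Genes were named through the platform's annotation table, with symbols checked by gene identifier against a RefSeq gene table (GRCm38.p6), used for names only, which changed 0 symbols. Of the transcript-level rows 25539 carry 1 gene symbol, 2300 carry several and 87991 have no gene named here. The named rows stand for 20259 genes, 3109 of them on more than 1 row. Named rows varied less over the 7 arrays (median SD 0.188) than the other rows (0.460). Slc1a2 is not reported, because its row also carries another gene. No coordinates are given, since the files name no build.

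Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the deposited log2 values of all rows with no covariate and no filter on dim rows. Benjamini-Hochberg adjustment ran over all rows of a table, with a threshold of 0.05 and two-sided tests. Differences are SOD1 G93A minus control in log2 units, with the moderated standard error and 95% interval. Gene lists were tested with limma's camera at a preset correlation of 0.01 on the brightest row of each gene, with an estimated correlation beside it. Fry, which asks whether a list moves at all and does not compare it with other genes, was run as a separate question. The 34 lists cover astrocyte identity and function, reactive states, stress, metabolic and immune pathways, and markers of other cell types that the sort could carry along. They hold 719 genes with the sex-linked genes, of which 622 have a row of their own. Some genes stand in more than 1 list, among them 2 of the 22 interferon genes and 4 of the 12 pan-reactive genes. The tests, the lists, the rule for named genes and the alternatives not marked below as added were chosen before the data were examined.

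The genes named are those past the threshold without overlap between the groups, up to 15 per direction with the largest change. Where fewer than 12 qualify, they are filled up to 12 rows in each direction with the smallest unadjusted p among rows of 1 gene without overlap and above the median level. Predicted genes, olfactory and vomeronasal receptors, small RNAs and ribosomal pseudogenes were left out of that choice. Up to 4 members with the smallest unadjusted p come from each list, and Sod1, Gfap, Aqp4 and Aldh1l1 are always given.

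The tests were checked on simulated values with the rows' own means and spreads and independent normal noise, in which 200 rows were shifted. For the transcript-level comparison of 115830 rows, limma called 0%, 39% and 57% of rows shifted by 1, 2 and 3 log2 units, and for the exon-level comparison of 20895 rows 0%, 36.5% and 80%. It made 0 calls without a shift, and beside the shifted rows it called up to 10 unshifted rows at either level. Camera called the interferon list, shifted by 0.3, in 20 of 20 rounds over 20259 genes, and called 0 lists in unshifted data, which were simulated without correlation between genes. Alternatives were renewed quantile normalisation, centring on array medians, filters on dim rows, an intensity trend with robust eBayes, array weights, the replicate number as a block, each array left out in turn, other thresholds and other list tests. The following were added after the data were seen: only rows that name 1 gene, rows with equal values left out, the Xist level or the first residual component as a covariate, and SOD1 G93A 4 and Control 3 left out together.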

Results

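Sorted cortical cells of SOD1 G93A mice (4 arrays) and control mice (3 arrays) were compared by exon microarray at postnatal day 120. SOD1 G93A mice carry a mutant human SOD1 transgene and develop a motor neuron disease used as a model of amyotrophic lateral sclerosis. The labels record hindlimb paralysis in the SOD1 G93A mice. Cells carrying enhanced green fluorescent protein were sorted from the dissociated cortex, and the title of the series names them cortical astroglia. Each array was summarised in a table of 115830 transcript-level rows and in a table of 20895 exon-level rows, so both tables describe the same 7 arrays. The comparison asks which transcripts differ in these cells once the mice are paralysed. The number of arrays limits the precision.

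The mouse Sod1 transcript was at the same level in both groups within the spread of the arrays. Its brighter row had a log2 value of 11.83 ± 0.16 (SD, n = 4) in SOD1 G93A and 11.92 ± 0.17 (SD, n = 3) in control. The log2 difference was -0.09 ± 0.15 (SE), with a limma adjusted p of 0.972. The other Sod1 row differed by -0.02 ± 0.11 (SE). The probes were designed for the mouse sequence, so these rows do not check whether the human transgene was present.

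Across the transcript-level table no transcript passed the test between SOD1 G93A and control cells. Aqp4, the water channel of astrocyte endfeet, differed by -0.03 ± 0.10 (SE) on the log2 scale, on a row that holds an equal value on 4 of the 7 arrays. Aldh1l1, a folate enzyme used as an astrocyte marker, differed by -0.13 ± 0.24 (SE), with a 95% interval from -0.69 to 0.44. Gfap, the intermediate filament of reactive astrocytes, was 0.43 ± 0.63 (SE) higher in the mean, with a 95% interval from -1.09 to 1.95. The arrays of the SOD1 G93A group differed more among themselves in Gfap than the group means did.

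With limma, 0 of 115830 rows passed an adjusted p of 0.05, and the smallest adjusted p was 0.284. At an unadjusted p under 0.05 there were 5521 rows, 4.77% of those tested, of which 2620 were higher and 2901 lower in SOD1 G93A. The groups did not overlap in 5253 rows, or 4.54%, against 5.71% given by chance for 4 against 3 arrays when no values are equal. Among the 25539 rows that name 1 gene, 0 passed, 460 (1.80%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.968. The groups did not overlap in 648 (2.54%) of these 25539 rows. A row with an equal value in both groups cannot count here, so the 5.71% is no exact chance share for these rows. The 95% interval of the difference lay within a 2-fold change either way for 84.1% of these named rows and for 54.4% of all rows. The smallest p values belonged to rows for which no gene is named here. Row 6808949 was 2.07 ± 0.14 (SE) higher in SOD1 G93A, with an adjusted p of 0.284, and row 7018295 was 2.93 ± 0.21 (SE) higher with the same adjusted p. In simulated data of the same size, limma called 39% of 200 rows shifted by 2 log2 units, 57% of those shifted by 3, and 0% of those shifted by 1. The shifted rows came from all rows, whose median SE was 0.279, against 0.159 for named rows. The simulation had no equal values and no array-wide differences, so its rates may not hold for the real arrays.

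**Figure D1:**
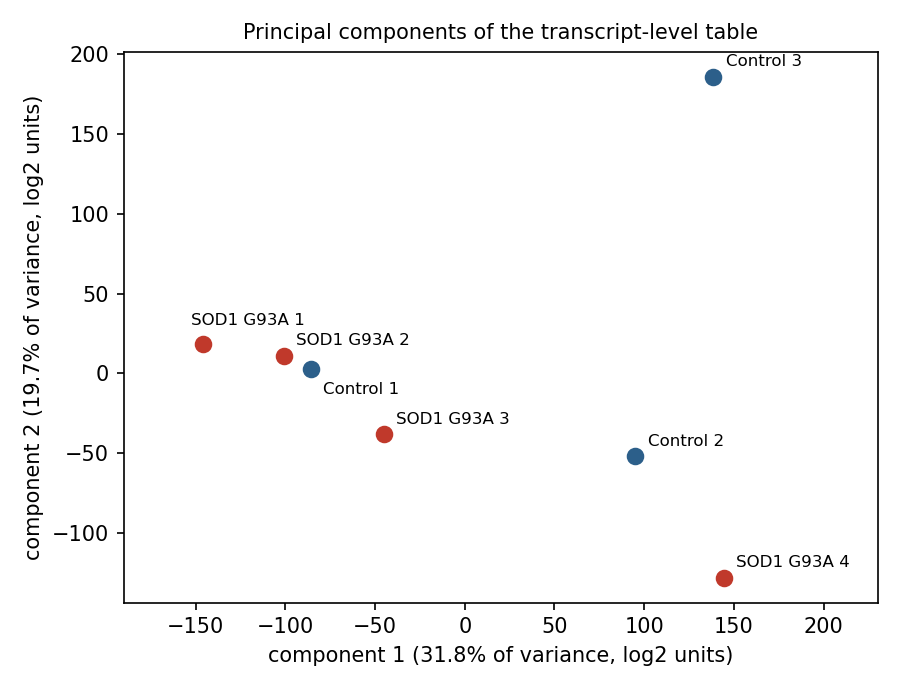
Arrays of the transcript-level table on the first principal component (31.8% of the variance) and the second (19.7%), both in log2 units, with SOD1 G93A in red and control in blue. SOD1 G93A arrays range from -146 to 144 on the first component and control arrays from -85.9 to 138, so the groups are not separated along it.

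Genes with no overlap between the groups and the smallest unadjusted p were taken up by rule, and none of them passed the test (limma adjusted p = 0.968 for each). Csprs, from a repeated gene cluster, was 1.91 ± 0.31 (SE) log2 units higher in SOD1 G93A, with 6 of its 7 rows on the higher side. Ubr3, a ubiquitin ligase, was higher by 0.81 ± 0.15 (SE), and all 11 of its rows had the same sign. Wiz, a zinc finger partner of histone methyltransferases, was higher on a pair of rows by 0.82 ± 0.19 (SE) and 0.73 ± 0.20 (SE), with 5 of 6 rows on that side. Tmem60 had the widest difference of the named genes, 3.23 ± 0.72 (SE), and 2 of its 3 rows shared the sign. Phf21a, a subunit of a histone demethylase complex, was higher by 1.36 ± 0.32 (SE), with all 3 rows on that side. Pde8b, which degrades cyclic AMP, was higher by 1.24 ± 0.29 (SE), and Rmnd1, needed for mitochondrial translation, by 1.24 ± 0.30 (SE), each with only 4 of 6 rows of that sign. Wdr45b, a phosphoinositide-binding autophagy protein, was higher by 1.28 ± 0.29 (SE), with both rows on that side. Wnt8b, a secreted Wnt ligand, was higher by 1.14 ± 0.25 (SE) on 1 row and on the other side on its second row. The long noncoding RNA Lncpint and Trh, the precursor of thyrotropin-releasing hormone, were higher by 0.48 ± 0.13 (SE) and 0.45 ± 0.12 (SE).

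Among the genes lower in SOD1 G93A by the same rule, Patz1, a zinc finger transcription factor, differed by -1.78 ± 0.31 (SE) on 1 of its 2 rows, and the other row had the opposite sign. Mtf1, the transcription factor that induces metallothioneins, differed by -1.53 ± 0.44 (SE), with both rows lower. Eprs, the glutamyl-prolyl-tRNA synthetase, differed by -1.28 ± 0.36 (SE), and Ndufb2, a subunit of respiratory complex I, by -0.96 ± 0.24 (SE), but each had a second row of the opposite sign. The retroviral gene Erv3 differed by -1.26 ± 0.36 (SE) and Pank4, of the pantothenate kinase family, by -1.12 ± 0.32 (SE), each with both rows lower. The histone gene H2aw differed by -0.94 ± 0.21 (SE). The pseudogene Magea9-ps and the zinc finger gene Zik1 differed by -0.84 ± 0.20 (SE) and -0.81 ± 0.21 (SE). For AI414108, Akip1 and Clrn3 the differences were -0.67 ± 0.16 (SE), -0.57 ± 0.16 (SE) and -0.55 ± 0.15 (SE), with both rows of Clrn3 lower.

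Genes of the pan-reactive and A1 astrocyte lists were uneven within the SOD1 G93A group. Of 12 measured pan-reactive genes, 8 were higher and 4 lower in the mean, and 0 passed the test over all rows or adjusted over the list alone. The mean of this list, set around each gene's average over the 7 arrays, was -0.47, -0.48, 0.73 and 0.72 log2 units on SOD1 G93A 1 to 4 and -0.36, -0.12 and -0.02 on Control 1 to 3. Osmr, the oncostatin M receptor, reached 8.47 and 7.78 on SOD1 G93A 3 and 4, against 6.23 and 6.45 on SOD1 G93A 1 and 2 and 6.03 to 6.50 in control. Lcn2, the secreted lipocalin of reactive astrocytes, was at 6.69 and 5.70 on the same arrays, at 4.01 and 3.99 on the others of the group, and at 4.18 to 4.24 in control. Gfap was at 9.58 and 10.04 against 7.98 and 7.57, with control values of 8.32 to 8.39. Osmr and Gfap held equal values on Control 2 and Control 3, and Lcn2 on Control 1 and Control 2. Their control ranges thus rest on fewer distinct values. The group differences were 0.89 ± 0.58 (SE) for Osmr, 0.90 ± 0.70 (SE) for Lcn2 and 0.62 ± 0.61 (SE) for the chemokine Cxcl10. The gene S1pr3, a sphingosine phosphate receptor, was at -0.20 ± 0.19 (SE).

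All 7 measured genes of the A1 list, a neurotoxic reactive state described after lipopolysaccharide, had positive differences, and 0 passed over all rows or adjusted over the list alone. The glucocorticoid-induced Fkbp5 differed by 0.65 ± 0.67 (SE), the extracellular Fbln5 by 0.46 ± 0.94 (SE), Amigo2 by 0.27 ± 0.45 (SE), and the complement inhibitor Serping1 by 0.18 ± 0.28 (SE). For the A2 list, described after ischaemia, 7 of 13 genes were higher and 6 lower. Against all other genes, limma's camera gave adjusted p values of 0.19 for the pan-reactive and A1 lists, both up, and 0.609 for the A2 list. With an estimated correlation the adjusted p was 0.919 for each of the 3 lists. Both the pan-reactive and the A1 list passed, up, without SOD1 G93A 1 (adjusted p = 0.0157) and without SOD1 G93A 2 (adjusted p = 0.0167 and 0.0390). Among the immediate early genes, which respond to stimulation and to cell handling, the list means were also highest on SOD1 G93A 3 and 4, at 0.18 and 0.30, and lay between -0.20 and 0.05 on the other 5. Other lists also had higher means on SOD1 G93A 3 and 4 than on SOD1 G93A 1 and 2, by less. Microglia markers were at -0.30, -0.15, 0.17 and 0.12 on SOD1 G93A 1 to 4, with 0.20 on Control 3. The oxidative stress list was at -0.19, -0.24, 0.14 and 0.24, the lysosome list at -0.16, -0.18, 0.13 and 0.12, and the glycolysis list at -0.20, -0.14, 0.06 and 0.14, while on Control 2 these 3 lists were at 0.21, 0.17 and 0.26.

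**Figure D2:**
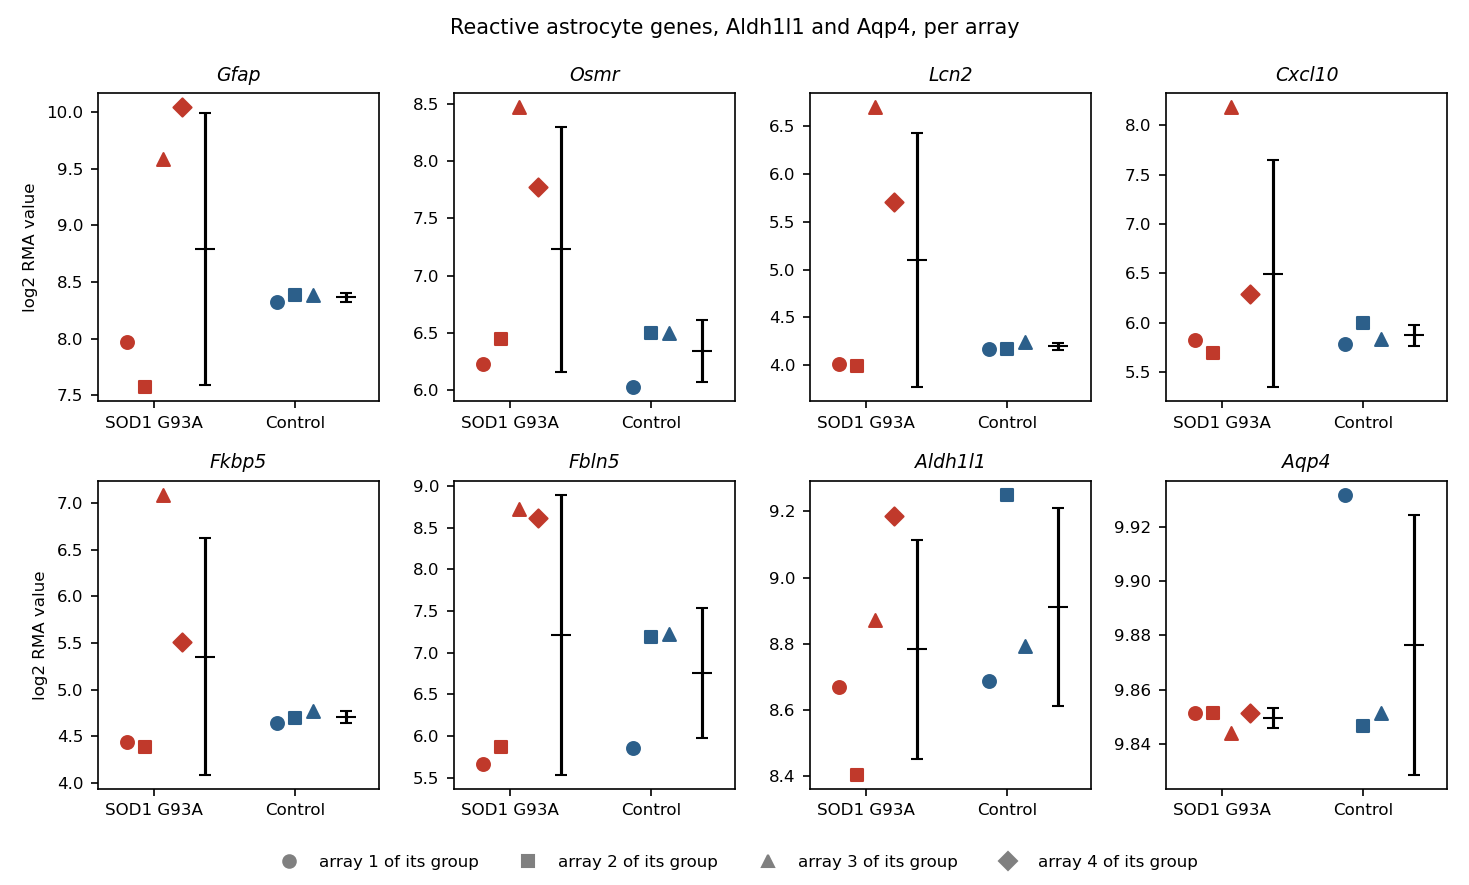
Log2 RMA values of 6 reactive astrocyte genes and of Aldh1l1 and Aqp4 on each array. The mean and SD of each group are in black, with a separate vertical axis per gene. Array numbers were not taken to pair the arrays across groups. Gfap lies at 9.58 and 10.04 on SOD1 G93A 3 and 4 and at 7.57 to 8.39 on the other 5 arrays.

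The interferon response was the only list of 34 to pass with camera at its preset correlation of 0.01. It moved up in SOD1 G93A with an adjusted p of 0.00262, and 17 of its 22 measured genes were higher. The call did not hold with an estimated correlation (adjusted p = 0.919). Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.937. Isg15, a ubiquitin-like protein induced by interferon, was 1.55 ± 0.47 (SE) higher with no overlap between the groups, at 5.93, 5.85, 6.50 and 4.46 on the SOD1 G93A arrays and 3.85 to 4.32 in control. Ifit3 and Ifit1, which bind foreign RNA, were higher by 0.86 ± 0.51 (SE) and 0.83 ± 0.53 (SE), and Oasl2, of the oligoadenylate synthetase family, by 0.21 ± 0.17 (SE). No member passed over all rows, and 0 passed adjusted over the list alone, where the smallest adjusted p was 0.329. The list mean was 0.53 on SOD1 G93A 3 and between -0.23 and 0.10 on the other SOD1 G93A arrays. The mean of the blood and leukocyte list was also highest on SOD1 G93A 3, at 0.29, where S100a8, a calcium-binding protein of neutrophils, was at 6.39 against 4.03 to 4.78 on the other 6 arrays. Without SOD1 G93A 3 the adjusted p was 0.303, and without Control 1 it was 0.0573. It was 0.329 without the lowest 50% of rows and 0.223 without rows that hold equal values on several arrays.

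**Figure D3:**
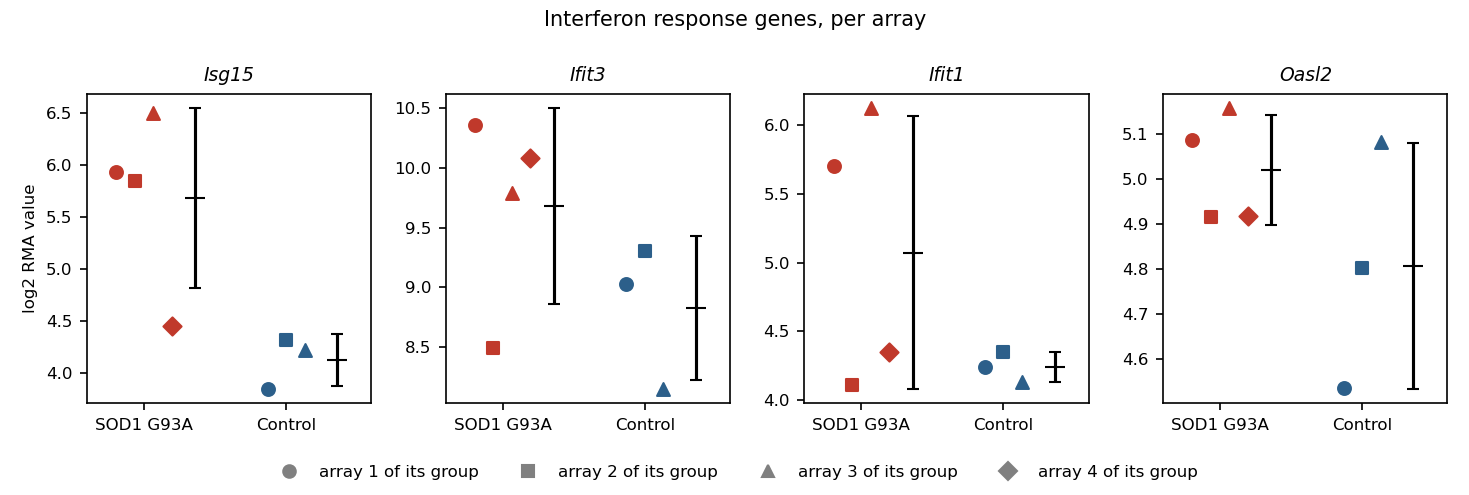
Log2 RMA values of the 4 interferon response genes with the smallest unadjusted p on each array, with the mean and SD of each group in black and a separate vertical axis per gene. Isg15 lies at 4.46 to 6.50 on the SOD1 G93A arrays and at 3.85 to 4.32 in control, while the groups overlap for Ifit3, Ifit1 and Oasl2.

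Markers of the oligodendrocyte lineage were mostly lower in SOD1 G93A, without passing the test. For oligodendrocyte precursors, 13 of 14 genes were lower (camera adjusted p = 0.12, down), among them the transcription factor Olig1 at -0.55 ± 0.23 (SE), Neu4 at -0.47 ± 0.23 (SE), the matrix protein Tnr at -0.29 ± 0.15 (SE) and Cacng4 at -0.26 ± 0.13 (SE). Of the mature oligodendrocyte genes, 14 of 17 were lower (adjusted p = 0.19, down), with the myelin gene Mog at -0.27 ± 0.13 (SE) and Opalin at -0.26 ± 0.12 (SE). Each had an adjusted p of 0.919 with an estimated correlation. The mean of the precursor list was 0.40 on Control 3 and between -0.23 and 0.08 on the other 6 arrays. Without Control 2 the precursor and mature lists passed (adjusted p = 0.0432 and 0.0268), and the precursor list also did without SOD1 G93A 2 (adjusted p = 0.0494) and with the first residual component as a covariate (adjusted p = 0.0165).

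Of the other cell types, microglia markers were lower for 14 of 19 genes (adjusted p = 0.585, down), including Tmem119 at -0.48 ± 0.19 (SE) and the fractalkine receptor Cx3cr1 at -0.35 ± 0.17 (SE). The disease-associated microglia list had 10 of 13 genes lower, with an adjusted p of 0.585. The neuron list was split, with 11 genes higher and 10 lower (adjusted p = 0.253, up). Its mean was -0.55 on Control 2 and between -0.01 and 0.23 elsewhere. Tubb3, the neuronal tubulin, lay at 3.52 on Control 2 and between 7.03 and 10.54 elsewhere, and Gad2, which makes GABA, lay at 3.18 on Control 2 and at 6.37 or above elsewhere. Without Control 1 the neuron list passed, up, with an adjusted p of 0.0339. Over all arrays its adjusted p was 0.919 with an estimated correlation. Ependymal and choroid plexus markers were lower for 9 of 10 genes, with an adjusted p of 0.617, and their list mean was 0.96 on Control 2 and 0.21 or less elsewhere. Klotho (Kl) and the chloride channel gene Clic6 were at 9.13 and 9.37 on Control 2. Endothelial, pericyte and blood lists gave adjusted p values of 0.753, 0.609 and 0.753.

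In energy metabolism, 37 of 43 genes of the mitochondrial respiratory chain were lower in SOD1 G93A, though the list did not pass (camera adjusted p = 0.185, down; adjusted p = 0.919 with an estimated correlation). Uqcrq, of complex III, differed by -0.48 ± 0.21 (SE), and the ATP synthase genes Atp5d and Atp5g1 by -0.44 ± 0.20 (SE) and -0.77 ± 0.42 (SE). The list mean was 0.26 on Control 2, the highest of the 7 arrays. The list passed, down, without SOD1 G93A 3 (adjusted p = 0.0433) and without Control 3 (adjusted p = 0.0213), as well as after renewed quantile normalisation (adjusted p = 0.0142). It also passed with array weights (adjusted p = 0.00209), with the first residual component as a covariate (adjusted p = 0.0171) and without SOD1 G93A 4 and Control 3 together (adjusted p = 0.00692). Cholesterol synthesis had 14 of 18 genes lower (adjusted p = 0.25), with Dhcr7, the last enzyme of the pathway, at -0.70 ± 0.32 (SE), and it passed, down, without SOD1 G93A 2 (adjusted p = 0.0211). Over all arrays the cholesterol list had an adjusted p = 0.919 with an estimated correlation. Glycolysis and lactate genes had 15 of 21 lower, with an adjusted p of 0.753.

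The astrocyte identity list showed no common direction, with 15 of 29 genes higher and 14 lower (adjusted p = 0.609). Slc7a10, a serine and alanine transporter, was at -0.35 ± 0.18 (SE), and Gpr37l1, a glial receptor, at -0.20 ± 0.17 (SE). Lists of astrocyte function gave adjusted p values of 0.753 for glutamate uptake, 0.253 for potassium, water and gap junctions, 0.609 for synapse modulation and phagocytosis, 0.792 for trophic factors and 0.753 for neurotransmitter receptors. In the receptor list P2ry1, a purinergic receptor of calcium signalling, was at -0.38 ± 0.11 (SE) with no overlap between the groups, and its adjusted p over the list alone was 0.261, the smallest of any listed gene. Thbs2, a synapse-promoting thrombospondin, was at -0.57 ± 0.21 (SE).

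Stress and degradation lists did not pass either. Adjusted p values were 0.753 for the lysosome, 0.753 for autophagy, 0.801 for the unfolded protein response, 0.609 for heat shock and 0.753 for oxidative stress and metallothionein. Atg12, a conjugate of autophagosome formation, was 1.19 ± 0.40 (SE) higher with no overlap, the chaperone Hspa1a was at -0.87 ± 0.36 (SE), Sdf2l1 of the endoplasmic reticulum at -0.36 ± 0.15 (SE), and Gsr, the glutathione reductase, 0.54 ± 0.22 (SE) higher. None passed over all rows or adjusted over the list alone. Adjusted p values were 0.506 for complement and antigen presentation, 0.616 for NF-kB and cytokine genes, 0.373 for immediate early genes, 0.753 for cytosolic ribosomal proteins, 0.642 for the cell cycle and 0.975 for extracellular matrix. Genes linked to amyotrophic lateral sclerosis gave 0.336, with Tardbp, which encodes the RNA-binding protein TDP-43, at 0.43 ± 0.22 (SE).

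For 14 lists the median, the mean and camera's direction did not all have the same sign. Camera compares a list with all other genes, and the median difference over all genes was -0.04. The 14 lists were astrocyte identity, blood, glutamate uptake, lysosome, autophagy, unfolded protein response, oxidative stress, NF-kB and cytokine, cell cycle, extracellular matrix, synapse modulation, trophic factors, neurotransmitter receptors and the genes linked to amyotrophic lateral sclerosis. Their smallest unadjusted p was 0.0989. Over the 34 lists 6 had an unadjusted camera p under 0.05, 1 passed after adjustment, and 0 passed with an estimated correlation or with fry. Testing for changes in either direction, fry gave a smallest adjusted p of 0.901.

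**Figure D4:**
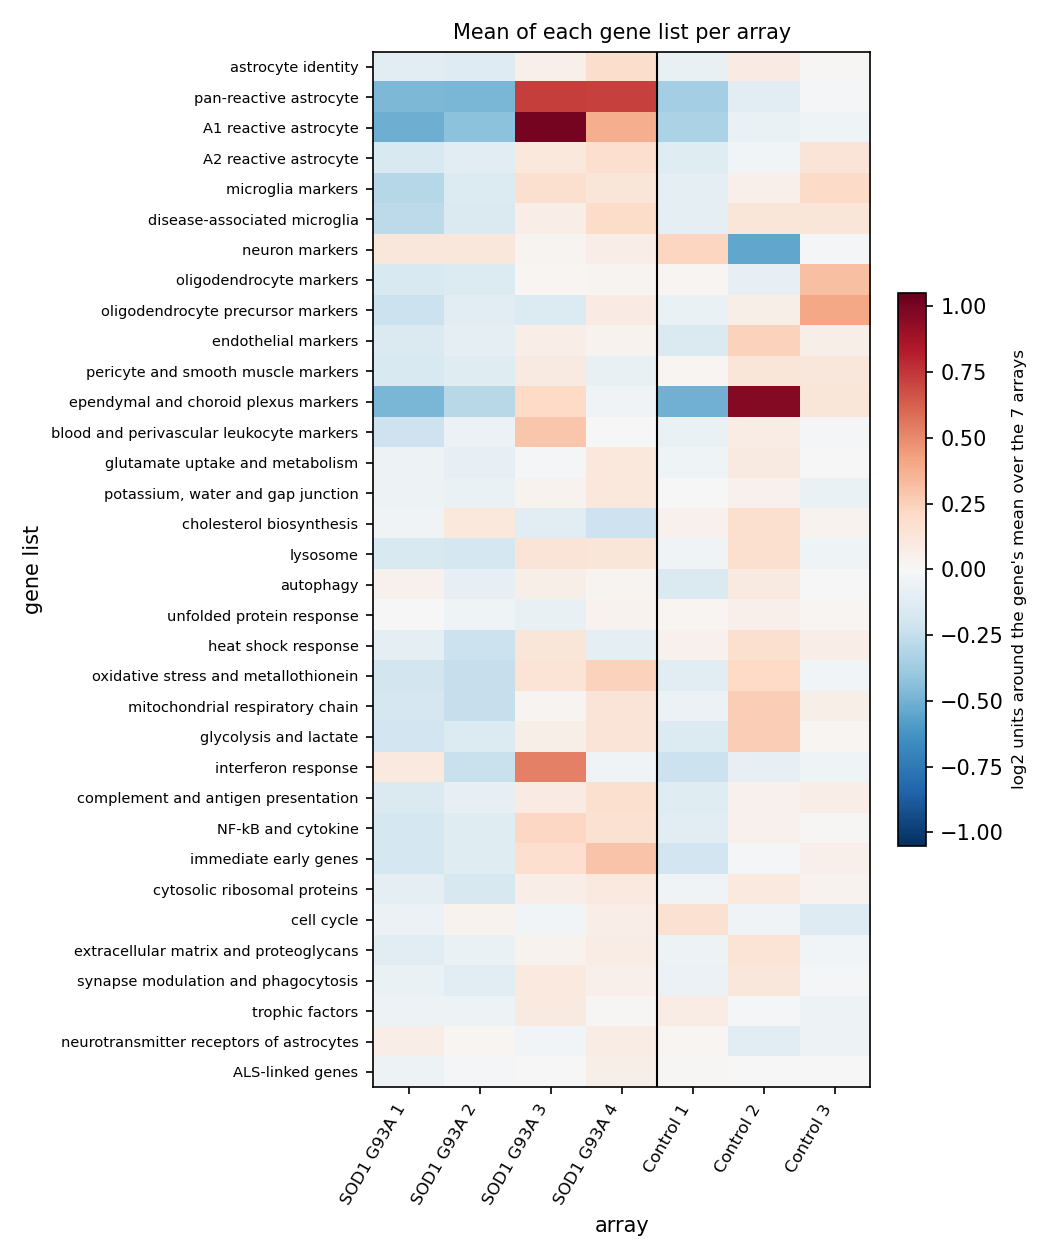
Mean of each of the 34 gene lists (rows) on each of the 7 arrays (columns), as colour in log2 units around each gene's mean over the arrays. The pan-reactive list is at 0.73 and 0.72 on SOD1 G93A 3 and 4, and the ependymal and choroid plexus list is at 0.96 on Control 2.

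At the exon level the same arrays gave no probe set past the threshold. With limma, 0 of 20895 rows passed, the smallest adjusted p was 0.547, and 797 rows had an unadjusted p under 0.05, of which 194 were higher and 603 lower in SOD1 G93A. The median difference of this table was -0.10 log2 units as deposited, 0.00474 after renewed quantile normalisation and 0.08 after centring each array on its median, so the excess of lower rows is relative to that shift. Row 4389512 was 2.88 ± 0.50 (SE) higher and row 4522440 differed by -2.16 ± 0.30 (SE), with adjusted p values of 0.983 and 0.761. No gene is named for exon-level rows, so unequal change across the exons of a gene was not analysed here.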

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

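The tests of technical explanations in this part were chosen after the results were seen, and 3 of their criteria, for the immediate early genes, for the groups without Control 3 and for RNA of both sexes, were reworded once the values were known. Of 200 SOD1 G93A values tested for an array standing apart from the other 3, 23 were marked, or 11.5%, against about 1 in 20 by chance. In 9 of the 23 the other 3 arrays hold exactly equal values, so that any deviation is marked. The array apart was SOD1 G93A 3 in 11 cases, SOD1 G93A 1 in 9, SOD1 G93A 2 in 2 and SOD1 G93A 4 in 1.

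On SOD1 G93A 3 the log2 values apart from the rest were 7.65 for Wdr45b, 8.04 for H2aw, 9.84 for Aqp4, 6.97 for Rrm1, 6.75 for Cfb, 4.28 for Lpl, 7.90 for Lama2, 9.82 for Ncan, 5.14 for Neurod2, 7.53 for Slc12a2 and 9.96 for the phagocytic receptor Mertk. On SOD1 G93A 1 they were 4.33 for H2-Aa, 5.70 for Tie1, 3.74 for Slco1a4, 5.18 for Cldn5, 6.67 for the lactate transporter gene Slc16a1, 6.05 for Gjc3, 5.61 for Acta2, 6.93 for Dag1 and 4.79 for Gdnf. SOD1 G93A 2 stood apart at 4.71 for B3gnt5 and 8.39 for Taf15, and SOD1 G93A 4 at 5.92 for Ier3.

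The pan-reactive and A1 lists had higher means on SOD1 G93A 3 and 4 than on each of the other 5 arrays, which the A2 list, at 0.11 on SOD1 G93A 3 and 0.14 on Control 3, did not. The NF-kB and cytokine list had the same order, at 0.21 and 0.16 against at most 0.045 elsewhere. So had the complement and antigen presentation list, at 0.084 and 0.17 against at most 0.071, and the immediate early genes. The order is thus not particular to reactive astrocyte genes. A technical trend along the first component alone was not decided. Control 3 lay about as far along it as SOD1 G93A 4 (139 against 144) with a pan-reactive mean lower by 0.73 ± 0.25 (SE over genes). This met the criterion against such a trend, of over 2 standard errors. It compares 1 array with 1 array, though, and the SE takes genes as independent, while their estimated correlation was 0.67. SOD1 G93A 3 had no array at its position, and differences along other components were not tested. For microglia carried through the sort, the markers stood at most 0.0918 ± 0.0851 (SE over genes) above the controls' median on these arrays. The pan-reactive genes stood 0.84 and 0.85 above it, and Control 3 had a higher microglia mean, 0.20, than either. The rise of the markers over control was smaller by over 2 standard errors, which again takes genes as independent. A contribution of microglia was not excluded, since their list mean was lower on SOD1 G93A 1 and 2, at -0.30 and -0.15. Blood leukocytes were not tested, and their list mean was highest on SOD1 G93A 3, at 0.29. A response to dissociation stays open, as the highest immediate early mean on the other 5 arrays minus that of SOD1 G93A 3 was -0.12 ± 0.21 (SE), within the spread. A course of disease that differs between mutant mice may also give this pattern and was not tested, since the labels give paralysis and the same age for the whole group.

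Oligodendrocyte precursor markers were highest on Control 3. Oligodendrocyte lineage cells carried through the sort are a candidate explanation, since the mature markers were also higher there by 0.37 ± 0.10 (SE over genes) than on the other 6 arrays, with 14 of 17 genes higher. Microglia markers were higher on Control 3 too, by 0.23 ± 0.06 (SE) with 14 of 19 genes higher, and pericyte markers by 0.14 ± 0.13 (SE). A lower share of the main cell type as the whole account met the criterion against it but was not decided. Of 4 other marker lists, 2 stood below the precursor rise of 0.47 ± 0.13 (SE) by more than 2 standard errors. They were those of neurons at -0.01 ± 0.13 (SE) and of endothelial cells at 0.07 ± 0.05 (SE). These values come from 1 array, and the SEs take genes as independent, while the precursor genes had an estimated correlation of 0.37. Whether the groups differ apart from this array stays open, as camera's unadjusted p without Control 3 was 0.116 with the same direction.

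Several sex-linked transcripts on SOD1 G93A 4 lay between the levels of the other arrays. Xist, transcribed from the inactive X chromosome, was at 11.85 on SOD1 G93A 1, 11.13 on Control 2 and 11.47 on Control 3, at 4.37 to 4.70 on SOD1 G93A 2, SOD1 G93A 3 and Control 1, and at 10.12 on SOD1 G93A 4, where it had 39.0% of the mean high level with nothing subtracted. Arrays with high and with low Xist thus stood in both groups, in unequal shares, and the main comparison had no covariate for this. Of 48 Y-linked rows 3 separated the other arrays by over 1 log2 unit, and all 3 were intermediate on SOD1 G93A 4. After the level of the low arrays was subtracted, Kdm5d, Eif2s3y and Uty were there at 62.6%, 26.3% and 10.7% of the high level. RNA of both sexes on one array may be involved but stays open, since no single share lay within 2 SD of the high level for all 3 and another Uty row was at 4.40 there and 5.33 to 6.73 elsewhere, and no biological explanation was tested.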

How the results depend on the processing

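Settings added after seeing the data were rows of 1 gene only, rows with equal values left out, the Xist or residual component covariate, and SOD1 G93A 4 and Control 3 left out together. The counts of 0 transcript-level and 0 exon-level rows held under all other settings run, except an unadjusted p under 0.05 with a 1.5-fold change, which gave 4139 and 797. Mouse Sod1 stayed between -0.18 and -0.01 under 19 alternatives. The number of lists called, 1 as reported, was 0 with an estimated correlation, with fry, without the lowest 50% of rows and without rows of equal values. It was 2 after quantile normalisation, with array weights and without SOD1 G93A 4 and Control 3, 3 with the residual component, and 1 to 5 with each array left out. The interferon list stayed up in all 23 alternatives and passed in 17, with adjusted p values from 2.81e-05 to 0.937. The cause was not tested, apart from the fewer rows or arrays that some settings use. With the replicate number as a block the counts were 0, 0 and 1 and Sod1 was at -0.17, and no call changed. Only SOD1 G93A has a replicate 4, so the block takes that array out of the group difference. Sod1 was likewise at -0.17 with SOD1 G93A 4 left out. Deviations of same-numbered arrays correlated at 0.28, -0.09 and -0.02. These values were not compared with those of differently numbered arrays, so they leave a pairing of the arrays undecided. The main tests take the arrays as unpaired.

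No named gene passed in any of 3093 alternatives, and 23 turned in sign. Of 782 list values 680 kept direction and side, 6 lost and 16 gained the threshold, and 80 turned in direction, none of them past it. The lists that turned had these adjusted p values, with the cause not tested. With the block, A2, complement and matrix were at 0.994 and heat shock at 0.819, and Uty and Fbln5 turned to 0.15 and -0.00695. After quantile normalisation, endothelial, glutamate, autophagy and trophic lists were at 0.919, blood, lysosome and matrix at 0.785, and the unfolded protein response at 0.63. Without the lowest 30% of rows, blood and matrix were at 0.892 and 0.941. Without the lowest 50%, blood was at 0.575, the unfolded protein response at 0.943, and NF-kB and matrix at 0.78. With array weights, identity and glutamate were at 0.863, lysosome at 0.544, the unfolded protein response at 0.996, oxidative stress at 0.732 and matrix at 0.849. Without rows of equal values, disease-associated microglia were at 0.678, endothelial at 0.91, complement at 0.967 and the disease-linked genes at 0.994. With Xist, the unfolded protein response was at 0.982. Without SOD1 G93A 4 and Control 3, identity and trophic lists were at 0.878, glutamate at 0.958, lysosome at 0.712, heat shock and oxidative stress at 0.931 and matrix at 0.779, while Amigo2, Mcm7, Ccdc153 and Kcnj10 were at -0.19, -0.22, 0.044 and -0.086. With fry, whose sign is set against no change and not against other genes and so is another quantity, 14 lists had the other sign, at 0.937 or 0.959.

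With each array left out, adjusted p values of lists that turned ran from 0.356 to 0.987 for blood, 0.684 to 0.987 for the unfolded protein response, 0.303 to 0.917 for glycolysis, 0.375 to 0.968 for receptors, 0.303 to 0.982 for endothelial, 0.303 to 0.896 for ribosomal, 0.112 to 0.982 for cell cycle, 0.304 to 0.979 for lysosome, 0.399 to 0.976 for autophagy, 0.317 to 0.98 for oxidative stress, 0.279 to 0.896 for NF-kB, 0.399 to 0.979 for matrix, 0.288 to 0.944 for heat shock, 0.0339 to 0.896 for neurons, 0.314 to 0.88 for pericytes and 0.134 to 0.979 for ependymal markers. Log2 differences ran from -0.23 to 0.0046 for Tgm1, -0.043 to 0.98 for Fbln5, -0.52 to 0.23 and -0.26 to 0.19 for rows of Uty, -0.042 to 0.00060 for Aqp4, -0.052 to 0.35 for Serping1, -0.26 to 0.042 for Aldh1l1, -0.16 to 0.022 for B3gnt5, -0.45 to 0.042 for Slco1a4, -0.58 to 0.030 for Cldn5, -1.77 to 0.15 for Kl, -1.18 to 0.21 for Clic6, -0.057 to 0.019 for the dimmer Sod1 row, -0.022 to 0.60 for Amigo2 and -0.000615 to 0.21 for Kcnj10. Signal over background was not analysed here, so dim rows are limited by it to an unknown degree. The test across the exons of a gene and its alternatives were not run, since no gene is named for exon-level rows.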

Other observations

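The test of the unadjusted count was chosen after that count had been seen. Markers of other cell types differed between the control arrays. On Control 2 the choroid plexus genes Kl and Clic6 were at 9.13 and 9.37, against at most 6.44 and 7.47 on the other 6 arrays, while the neuronal genes Tubb3 and Gad2 were at 3.52 and 3.18. The mean of the neuron list was lowest on Control 2, at -0.55, and between -0.01 and 0.23 on the other 6 arrays. Single neuron markers beside Tubb3 and Gad2 were mixed there. Snap25 at 6.01, Vsnl1 at 4.78 and Stmn2 at 4.97 were lowest of the 7 arrays on Control 2. Npy at 9.14 and Nefm at 7.93 lay within the range of the other arrays. Gabrb1, a GABA receptor subunit, was at 7.37 on Control 2, 8.59 on Control 3 and 9.35 to 10.56 elsewhere. Klf4, a transcription factor of the immediate early list, was at 8.47, 8.08 and 9.76 on SOD1 G93A 1 to 3, at 5.66 on SOD1 G93A 4 and at 5.18 to 6.44 in control, a group difference of 2.04 ± 0.94 (SE) that did not pass the test. Ccl2, a chemokine for monocytes, was at 5.82 and 7.30 on SOD1 G93A 3 and 4 and at 4.62 to 4.97 on the other 5 arrays.

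All 35 splits of the 7 arrays into 4 and 3 were compared with the real one. At an unadjusted p under 0.05, 11 of 35 splits reached the real 5521 transcript-level rows, with 18005 as the highest other. For lists called by camera, 31 of 35 reached the real 1, with 18 as the highest other. Chance is thus not excluded for these 2 counts. The real counts past the threshold were 0 at both levels, which all 35 splits reach by construction, so the splits say nothing of chance there; the highest others were 122 transcript-level rows and 1 exon-level row. The split of SOD1 G93A 4, Control 2 and Control 3 from the rest gave the 122 rows, against the real 0, and the 18005, several times the real 5521. This points to a structure of the samples that crosses the groups. The split was picked as the highest of 35, though, and its 3 arrays are also those with positive values on the first component. It is thus no independent test of that structure. Xist was at 10.12, 11.13 and 11.47 on these 3 arrays, but also at 11.85 on SOD1 G93A 1, outside the split. Whether sex plays a part in this structure was not tested. At the exon level the same 3 arrays had the highest medians, 4.67, 4.29 and 4.36, against 3.69 to 3.87 on the other 4. They include Control 2 and Control 3 but only SOD1 G93A 4 of the mutant arrays. This array-wide difference is thus unevenly spread over the groups and partly confounded with every group difference given here.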
